A study of Homo sapiens with 39 samples.

How the data were processed

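RNA from 39 cultures of the breast cancer lines MCF-7 and T47D was measured on Affymetrix gene arrays, 13 groups of 3 biological replicates. Cells had been treated for 16 h with vehicle, palbociclib, ribociclib or abemaciclib, and the resistant sublines had grown in 1 µM drug before. The deposited table holds log2 values that the authors computed by RMA in R 3.6.1. The genome build, the annotation version and which arrays were normalized together are not given in the sources used here. Values run on the log2 scale of RMA, which compresses low levels, and come without detection calls. Groups were taken from the sample labels, which title the MCF-7 control arrays parental and the T47D ones vehicle and describe both as treated with vehicle (DMSO) for 16 h, and replicate numbers are names without an order.

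The table has 53617 probe sets. Of these 23866 carry 1 gene symbol, 1852 several and 27899 none, and those without a single symbol were left out because their signal cannot be given to 1 gene. The rest name 22392 genes, and for 630 genes with several probe sets the one with the highest mean was used. Probe set positions were not in the table, so neighbouring genes were taken by their start in the RefSeq gene table. A gene was tested when its mean in at least 1 group lay above 3.503 on the log2 scale, the median of the medians of the arrays, which left 14795 genes in MCF-7, 15118 in T47D and 15718 in the 2 lines together.

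Differences were fitted with limma 3.58.1 in R 4.3.3 as linear models with a mean per group, and with variances moderated with a trend on the mean level and robust to genes of unusual spread. Each line was fitted with all its arrays, 18 for MCF-7 and 21 for T47D, and differences of drug effects between the lines used all 39. Of 25 comparisons, 11 set drug-treated or resistant cells against vehicle, 5 set resistant against parental cells in the same drug, 6 set drugs of a line against each other and 3 set drug effects of the lines against each other. Adjusted p values are Benjamini-Hochberg values over the genes tested, and a gene is called when its adjusted p is below 0.05. Precision is set by the number of arrays, 3 per group, and most differences of single genes in the report carry their SE. Where no difference between drugs was called the 95% interval is given instead.

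For 22 gene lists written beforehand the camera test of limma asked whether members moved further than other genes, with its preset correlation of 0.01 between members and once more with a correlation estimated for each list. Its 550 tests were adjusted over the 22 lists of a comparison. Members called over all genes were counted, and so were members called when p was adjusted over the list alone. Lists share some members, so their results are not independent.

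Genes are named by a rule. For vehicle and resistance comparisons it takes the 6 largest rises and the 6 largest falls among called genes whose arrays do not overlap between the groups, and for drug against drug and for effect differences the 3 largest each way. It adds up to 4 called members of each list with the largest differences, and a panel of CDK4, CDK6, CCND1, CCNE1, CCNE2, RB1, CDKN1A, E2F1, MKI67, ESR1 and PGR. The design, the lists, this rule and most alternatives were chosen before the data were examined.

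The calls were tested on simulated data with 200 changed genes. At log2 sizes of 0.5, 1 and 2 the fit recovered 47.76, 74.63 and 100% for palbociclib against vehicle in MCF-7, and 53.73, 88.06 and 100% in T47D. For resistant against parental T47D cells in palbociclib it recovered 56.72, 83.58 and 96.97%, and for the palbociclib effect difference 25.37, 71.64 and 96.97%. False calls were 6.33, 3.01, 5.39 and 5.15% of the calls made. The simulation gave all arrays the same independent spread for each gene. The real MCF-7 vehicle arrays spread more, with SD 0.43 for their mean of DNA replication and G1/S genes against 0.01 with palbociclib. The rates therefore do not describe palbociclib against vehicle in MCF-7 or the palbociclib effect difference.

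Genes called by several drugs were counted by direction, beside the number that independent calls give and the number from 20 simulations of unchanged groups that share the vehicle arrays. Alternatives tried were quantile normalization, no filter on level, the mean of all probe sets of a gene, the replicate number as a block, a fit of only the groups compared, and omission of each replicate in turn. Other splits of the arrays into groups of the same sizes were also fitted.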

Results

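MCF-7 and T47D are estrogen receptor positive breast cancer lines. Each was given vehicle or a low dose of 1 of 3 inhibitors of the cell-cycle kinases CDK4 and CDK6 for 16 h, and its RNA was read on gene arrays. MCF-7 cells received palbociclib at 75 nM, ribociclib at 200 nM or abemaciclib at 40 nM, and T47D cells received 40, 100 and 20 nM of the same drugs. Resistant sublines had grown in 1 µM drug until the day before the assay. They were plated without drug and then treated for 16 h, with ribociclib or abemaciclib for MCF-7 and with all 3 drugs for T47D. Doses are stated per line, not separately for resistant cells. The series has 13 groups of 3 arrays, 18 arrays of MCF-7 and 21 of T47D. Single-gene differences below are of log2 group means, n = 3 arrays per group unless some are left out. Most carry a standard error (SE), some an adjusted p. List values are medians over the members of a list. The genes named for the largest changes have no overlap between the arrays of the 2 groups, which unchanged genes show in 10% of comparisons of 3 against 3. Where 1 of the 2 groups lies under 3.503, the level a gene had to pass to be tested, the difference is given on the log2 scale with no fold.

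In T47D all 3 drugs lowered every member of the 2 lists of proliferation genes. The 65 DNA replication and G1/S genes were all lower, with medians of -2.14 for palbociclib, -1.44 for ribociclib and -2.19 for abemaciclib (adjusted p = 3.8e-75, 6.5e-50 and 8.4e-70). All 62 G2/M and mitosis genes were lower too, with medians of -2.35, -1.52 and -1.73 (adjusted p = 3.8e-75, 2.5e-51 and 1.4e-60). Adjusting over each list alone left these counts as they were. The replication-dependent histones, which package newly copied DNA, fell at 8, 8 and 7 of 11 members (medians -2.08, -1.35 and -1.79, adjusted p = 1.3e-07, 6.3e-05 and 9.6e-05). CCNE2, the cyclin E2 that drives entry into S phase, fell by 4.89, 2.84 and 5.41 on the log2 scale (SE 0.14). These are falls of 29.6-fold, 7.16-fold and 42.4-fold.

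**Figure D1:**
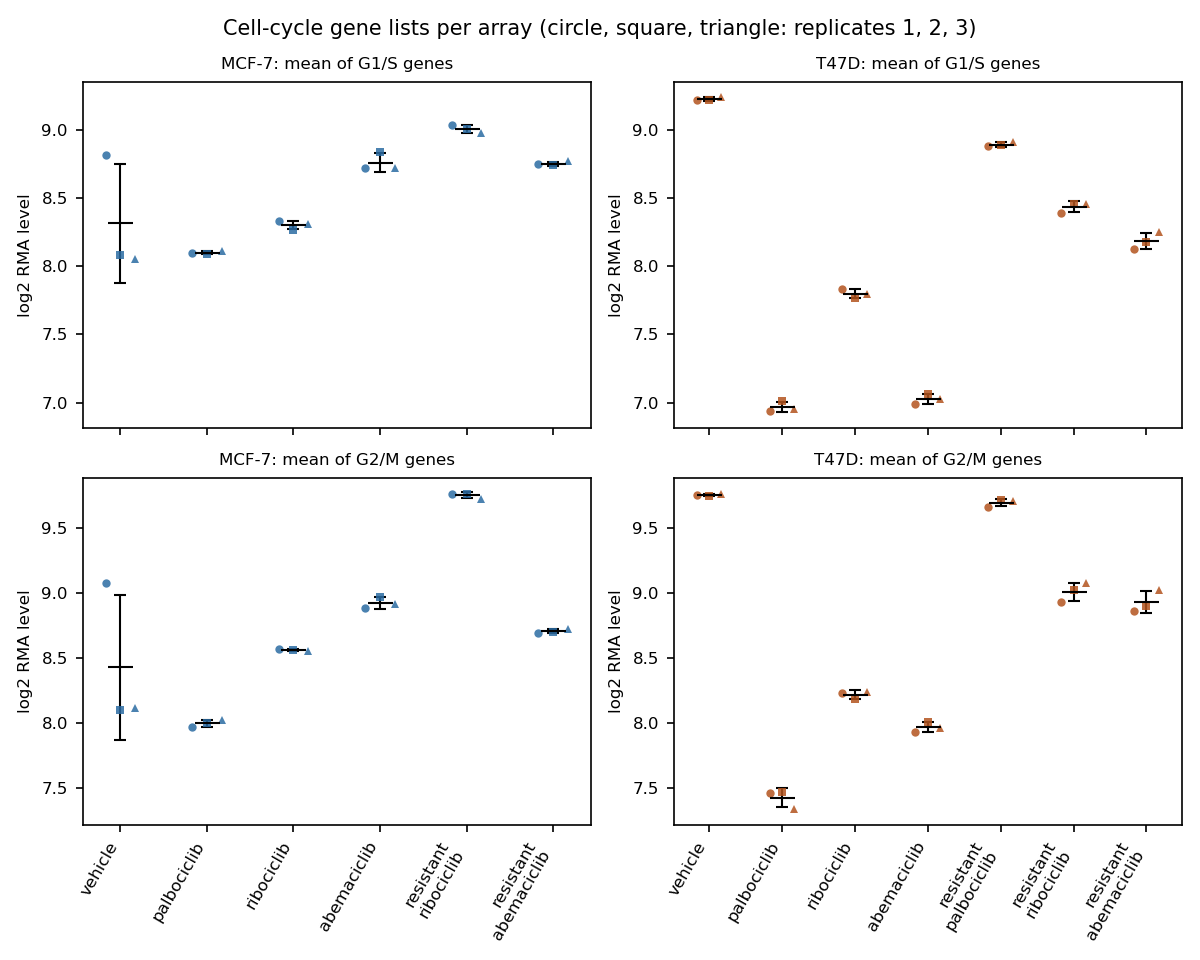
Mean log2 level per array of the DNA replication and G1/S genes and of the G2/M and mitosis genes in the 13 groups. Points are arrays, bars are the mean with SD, n = 3.

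Palbociclib in T47D left 5065 genes called, 2643 higher and 2422 lower, and 594 of them were at least 2-fold lower. H1-5, a linker histone of dividing cells, fell by 5.66 (SE 0.17) on the log2 scale, and FAM111B, a protease active in S phase, fell by 5.62 (SE 0.16). H2BC14, a core histone, fell by 5.22 (SE 0.10) on the log2 scale. MCM10, which starts replication, and EXO1, a DNA repair nuclease, changed by -4.25 (SE 0.08) and -4.24 (SE 0.10). MKI67, the common proliferation marker, changed by -2.93 (SE 0.08, adjusted p = 7.9e-20). E2F1, the transcription factor held by RB1, changed by -2.69 (SE 0.11), and CCNE1, cyclin E1, by -1.80 (SE 0.12). The largest rises were in TBX18, a developmental transcription factor (2.76, SE 0.14, 6.75-fold), FZD6, a Wnt receptor (2.58, SE 0.09, 6.00-fold), and NEGR1, a cell adhesion molecule (2.45, SE 0.29).

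Ribociclib in T47D left 5974 genes called, 2980 higher and 2994 lower, with 532 of the latter at least 2-fold lower. CYP4X1, a cytochrome P450, fell by 3.84 (SE 0.16) and the histone gene H2AC14 by 3.01 (SE 0.31) on the log2 scale. SPC25, a kinetochore protein, and CDK1, the mitotic kinase, changed by -2.80 (SE 0.13) and -2.42 (SE 0.09). MKI67 changed by -1.55 (SE 0.08, adjusted p = 4.3e-14) and E2F1 by -1.53 (SE 0.11). TBX18 rose 7.29-fold (2.87, SE 0.14) and FZD6 7.83-fold (2.97, SE 0.09).

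Abemaciclib in T47D left 5587 genes called, 2998 higher and 2589 lower, 587 of these at least 2-fold lower. FAM111B changed by -5.26 (SE 0.16), H2BC14 by -4.52 (SE 0.10), H1-5 by -4.30 (SE 0.17) and DTL, an S-phase ubiquitin ligase adaptor, by -4.20 (SE 0.07). MKI67 was 4.29-fold lower (-2.10, SE 0.08, adjusted p = 4.5e-17), E2F1 7.28-fold (-2.86, SE 0.11) and CCNE1 3.89-fold (-1.96, SE 0.12). Among the rises were FZD6 (3.03, SE 0.09), TBX18 (2.91, SE 0.14) and ALB, the serum protein albumin (2.35, SE 0.21).

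Other lists changed less in T47D. Of 28 genes of the CDK4/6, cyclin and RB pathway 13, 10 and 14 were lower with palbociclib, ribociclib and abemaciclib, and 3, 3 and 5 higher (adjusted p = 0.0001, 0.0048 and 9.6e-05). Members are partly the same genes as in the G1/S list. Of 40 estrogen-responsive genes 16, 14 and 14 were lower (medians -0.15, -0.11 and -0.13, adjusted p = 0.0024, 0.0105 and 0.0104). The last 2 calls are lost with an estimated correlation, adjusted p = 0.0649 and 0.0569. PDZK1, a scaffold protein induced by estrogen, fell by 2.41, 2.67 and 2.46 (SE 0.25) and ELOVL2, a fatty acid elongase, by 2.10, 2.51 and 2.23 (SE 0.13) on the log2 scale, while ESR1, the estrogen receptor itself, rose by 0.55, 0.57 and 0.60 (SE 0.08). Luminal epithelial genes were higher at 11, 10 and 12 of 23 members (adjusted p = 0.0058, 0.0177 and 0.0088). Ribociclib and abemaciclib lose that call with an estimated correlation, adjusted p = 0.0894 and 0.0569.

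Of 40 interferon-stimulated genes 14, 21 and 14 were lower in T47D with palbociclib, ribociclib and abemaciclib, at medians of -0.29, -0.33 and -0.17 (adjusted p = 0.00024, 0.00035 and 0.0042). None of the 3 calls holds with an estimated correlation, adjusted p = 0.298, 0.322 and 0.426. IFI27, a mitochondrial interferon-induced protein, fell by 2.49, 2.38 and 2.02 on the log2 scale (SE 0.20), and PLSCR1, an antiviral membrane protein, by 1.51, 1.62 and 1.78 (SE 0.16). NF-kB and secretory cytokine genes were lower at 6, 5 and 5 of 12 members (adjusted p = 0.008, 0.0219 and 0.0105). An estimated correlation keeps the palbociclib call and gives adjusted p = 0.0722 and 0.0569 for the others. The ribociclib call also ends with no filter (adjusted p = 0.0537). TNFAIP3, a brake on NF-kB, changed by -1.61, -1.55 and -1.35 (SE 0.22). Ribosomal protein genes were higher at 5, 9 and 7 of 21 members (adjusted p = 0.0446, 0.0226 and 0.0095). With an estimated correlation they gave adjusted p = 0.186, 0.146 and 0.0836. The palbociclib call also ends without vehicle replicate 2 or 3 (0.0621 and 0.0737) or palbociclib replicate 3 (0.0819).

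Receptor tyrosine kinase genes in T47D were lower with palbociclib at 8 of 17 members (median -0.34, adjusted p = 0.0188), among them MET, the receptor of hepatocyte growth factor (-1.16, SE 0.24). Without palbociclib replicate 1 the list gives adjusted p = 0.0525. MAPK and AP-1 output genes were lower at 10 of 23 members with palbociclib (adjusted p = 0.0446), which becomes 0.0505 and 0.0819 without palbociclib replicate 2 or 3 and 0.0581 and 0.0548 without vehicle replicate 1 or 3. Abemaciclib gave adjusted p = 0.0451 for this list, with 0.0766 without abemaciclib replicate 1 and 0.0517 and 0.052 without vehicle replicate 1 or 3. These become, with an estimated correlation, adjusted p = 0.149 and 0.136. The p53 target genes were not called with any drug (adjusted p = 0.338, 0.357 and 0.559), although TP53INP1, a p53-induced autophagy gene, rose by 1.61, 1.38 and 1.49 (SE 0.08). DDIT4, a stress-induced mTOR inhibitor on the list of ATF4 and unfolded protein response genes, rose by 2.10, 1.96 and 2.32 (SE 0.09), and that list was not called (adjusted p = 0.684, 0.813 and 0.834).

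With palbociclib, T47D lists without a call were antigen presentation (adjusted p = 0.933), mesenchymal (0.921), basal epithelial (0.897) and cholesterol synthesis genes (0.386). The same holds for hypoxia and glycolysis (0.933), lysosome and autophagy (0.719), aryl hydrocarbon receptor and drug handling (0.792), and fibroblast and leukocyte marker genes (0.888). CDK6, a target of the drugs, was at 4.60 (SD 0.10) with vehicle and not called with any of them (-0.16, -0.07 and 0.02, SE 0.21, adjusted p = 0.620, 0.839 and 0.955). Oxidative phosphorylation genes were not called with palbociclib or ribociclib (adjusted p = 0.221 and 0.0542) and were higher with abemaciclib at 7 of 21 members (adjusted p = 0.0288), 0.0571 without abemaciclib replicate 1 and with an estimated correlation adjusted p = 0.187. RB1, the pocket protein that CDK4 and CDK6 phosphorylate, fell by 0.38, 0.60 and 0.59 on the log2 scale (SE 0.08).

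**Figure D2:**
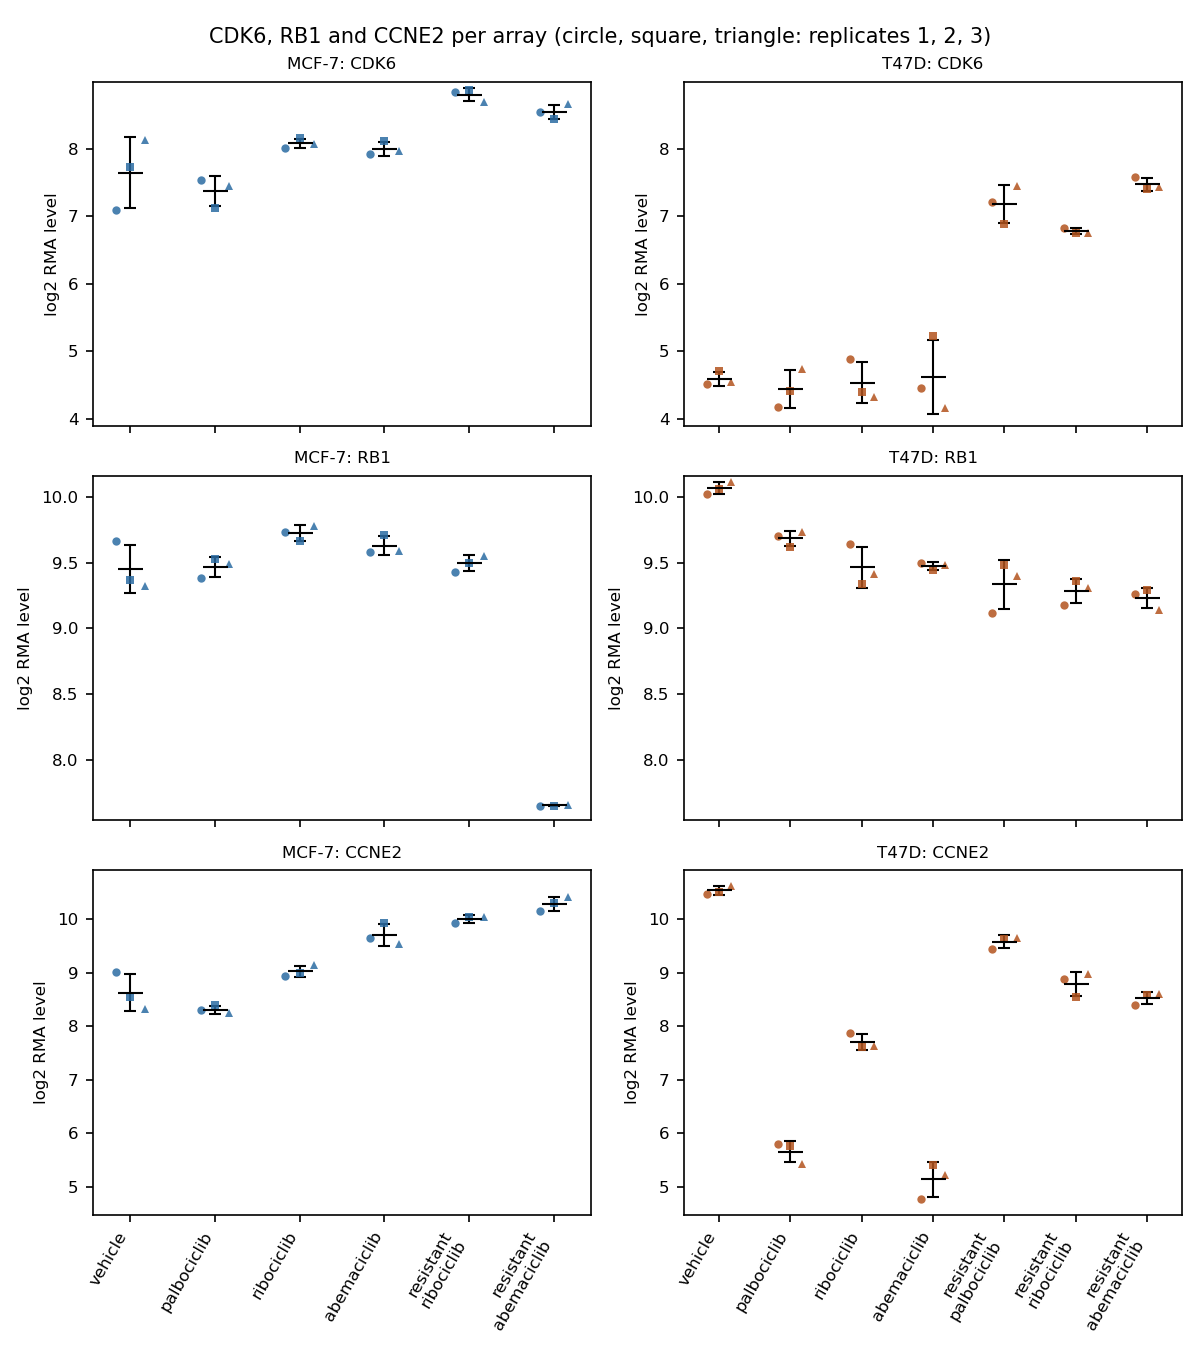
Log2 level per array of CDK6, RB1 and CCNE2 in the 13 groups. Points are arrays, bars are the mean with SD, n = 3.

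The 3 MCF-7 vehicle arrays did not behave alike. Replicate 1 has a mean correlation of 0.9708 with the other 2, which correlate at 0.9895, and of 0.987 with the palbociclib arrays. Its mean of the G1/S genes is 8.82 against 8.08 and 8.05, and of the G2/M genes 9.07 against 8.10 and 8.11. For the p53 targets it is 7.31 against 7.85 and 7.91, for the MAPK and AP-1 genes 6.26 against 7.21 and 7.32, and for oxidative phosphorylation 8.77 against 8.42 and 8.45. In T47D the vehicle means of the G1/S genes lie between 9.22 and 9.24. The MCF-7 vehicle replicates 2 and 3 have mean correlations of at most 0.9729 and 0.9721 with another MCF-7 group. Their G1/S means lie no higher than the 8.1 of the MCF-7 palbociclib arrays. Which MCF-7 vehicle arrays deviate therefore stays open. For gene groups called against MCF-7 vehicle below, medians without replicate 1 and with it alone follow the value from all 3 arrays.

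Palbociclib in MCF-7 left 2752 genes called, 1823 higher and 929 lower. The count is 5740, 986 and 1030 without vehicle replicate 1, 2 or 3 and 1524, 1513 and 1572 without palbociclib replicate 1, 2 or 3. It is 775 with vehicle replicate 1 alone, and 7 when only the 6 arrays compared are fitted. MT1F, a metal-binding metallothionein, rose 4.62-fold from 7.11 (SD 0.43) to 9.32 (SD 0.12, adjusted p = 7.7e-07), and FGF18, a growth factor, rose by 1.79 (SE 0.25, adjusted p = 0.00036). H2BC14 fell by 1.74 (SE 0.07, adjusted p = 2.7e-11), TYMS, which makes thymidylate for replication, by 0.96 (SE 0.09), and WDR76, a replication-linked repeat protein, by 1.15 (SE 0.17) on the log2 scale. CCNE1 rose by 0.71 (SE 0.14). MKI67 was not called (-0.41, SE 0.20, adjusted p = 0.158), nor were E2F1 (-0.31, SE 0.21, adjusted p = 0.327) and CDKN1A, the p21 inhibitor (-0.38, SE 0.20, adjusted p = 0.204). E2F1 is called without vehicle replicate 2 (-0.64, adjusted p = 0.0329) and against replicate 1 alone (-0.98, adjusted p = 0.00026), but is 0.02 without replicate 1 (adjusted p = 0.935). MKI67 goes in the same way from -1.2 against replicate 1 alone to -0.01 without it (adjusted p = 0.877). CDKN1A is called without vehicle replicate 1 (-0.66, adjusted p = 0.0027) and is 0.18 against it alone. A fit of only the 6 arrays ends the calls of FGF18 (adjusted p = 0.127), TYMS (0.0601), WDR76 (0.172) and CCNE1 (0.18).

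G1/S genes with palbociclib in MCF-7 gave 1 higher and 17 lower of 65 (18 lower adjusted over the list alone) at a median of -0.23 (adjusted p = 6.3e-09). Their median is 0.04 without vehicle replicate 1 and -0.70 with replicate 1 alone, where 59 are lower. G2/M genes gave 25 lower of 62 (30 over the list alone), median -0.41 (adjusted p = 7.2e-15), and -0.07 and -1.11 under the same changes of vehicle. Neither is called with an estimated correlation, adjusted p = 0.532 and 0.512. Histones were lower at 7 of 11 members (8 over the list alone; median -0.64, adjusted p = 6.3e-09), and with an estimated correlation adjusted p = 0.0664. Their median stays negative with either choice of vehicle, -0.44 and -1.2.

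Of 25 p53 targets 9 were lower in MCF-7 with palbociclib (13 over the list alone; median -0.29, adjusted p = 6.9e-08), and with an estimated correlation adjusted p = 0.360. The median is -0.46 without vehicle replicate 1 and 0.01 with that array alone. DDB2, a DNA damage sensor, fell by 1.12 (SE 0.17) on the log2 scale, and replicate 1 alone gives -0.54, while a fit of only the 6 arrays gives adjusted p = 0.172. Oxidative phosphorylation genes were higher at 11 of 21 members (15 over the list alone; median 0.29, adjusted p = 0.0012), with medians of 0.40 without vehicle replicate 1 and 0.02 against it alone, with an estimated correlation adjusted p = 0.512. MAPK and AP-1 genes were lower at 7 of 24 members (adjusted p = 0.018; estimated correlation, adjusted p = 0.532), with a median of -0.15 that is -0.43 without vehicle replicate 1 and turns to 0.29 against it alone. Ribosomal protein genes were lower at 2 of 21 members (0 over the list alone; median -0.14, adjusted p = 0.0127), with an estimated correlation adjusted p = 0.403, and their median is -0.23 without vehicle replicate 1 and -0.01 against it alone. For estrogen-responsive genes the median is 0.01 and the mean -0.10 (adjusted p = 0.297).

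Ribociclib in MCF-7 left 4482 genes called, 2609 higher and 1873 lower (6376 without vehicle replicate 1, 2890 against replicate 1 alone, 1564 when only these 6 arrays are fitted). KBTBD8, a ubiquitin ligase adaptor, rose 6.35-fold (2.67, SE 0.31, adjusted p = 1.1e-05; 1.48 against replicate 1 alone). NT5E, the surface nucleotidase CD73, and CDH5, an endothelial cadherin, rose by 1.94 (SE 0.22) and 1.80 (SE 0.23). ABCG2, a drug efflux pump, rose by 1.24 (SE 0.06, adjusted p = 2.8e-09), GCLM, an enzyme of glutathione synthesis, by 1.06 (SE 0.13) and CYP1A1, a detoxifying oxidase, by 0.89 (SE 0.20). EGR1 and EGR3, immediate early transcription factors, fell by 2.56 (SE 0.41) and 2.55 (SE 0.30) on the log2 scale, and EGR1 fell by 0.91 against replicate 1 alone. PGR, the progesterone receptor, changed by -1.76 (SE 0.31; -0.61 against replicate 1 alone). MKI67 was not called (-0.05, SE 0.20, adjusted p = 0.890), but without vehicle replicate 1 it is higher by 0.35 (adjusted p = 4.8e-05).

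Abemaciclib in MCF-7 left 4342 genes called, 2494 higher and 1848 lower (6490 without vehicle replicate 1, 2818 without replicate 3, 1615 against replicate 1 alone, 612 when only these 6 arrays are fitted). KBTBD8 rose by 2.55 (SE 0.31), FGF18 by 1.86 (SE 0.25), CYP1A1 by 1.31 (SE 0.20) and ABCG2 by 1.06 (SE 0.06). CCNE2 rose by 1.08 (SE 0.13, adjusted p = 3.2e-05; 0.69 against replicate 1 alone). CA11, a carbonic anhydrase relative, fell by 2.55 (SE 0.35), EGR3 by 2.47 (SE 0.30) and PGR by 1.89 (SE 0.31) on the log2 scale. MKI67 (0.40, SE 0.20, adjusted p = 0.136) and E2F1 (0.37, SE 0.21, adjusted p = 0.207) were not called, but without vehicle replicate 1 they are higher by 0.80 (adjusted p = 6.3e-10) and 0.70 (adjusted p = 0.00062). PGR has adjusted p = 0.0523 in a fit of only the 6 arrays.

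The proliferation lists in MCF-7 turn with the vehicle arrays used. G1/S genes gave 6 higher and 8 lower of 65 with ribociclib (median -0.02, adjusted p = 0.283), and the median is 0.21 without vehicle replicate 1 and -0.49 against it alone. With abemaciclib 37 were higher and 1 lower (45 and 1 over the list alone; median 0.41, adjusted p = 9.9e-08), with 0.63 and -0.08 under the same changes. G2/M genes gave 11 higher and 3 lower with ribociclib (median 0.19, adjusted p = 0.336; 0.53 and -0.47) and 37 higher with abemaciclib (41 over the list alone; median 0.53, adjusted p = 9.5e-08; 0.90 and -0.11). Both abemaciclib calls are lost with an estimated correlation, adjusted p = 0.618. Histones with ribociclib were lower at 5 of 11 members (adjusted p = 0.004; estimated correlation, adjusted p = 0.313), and their median of -0.42 is -0.17 without vehicle replicate 1, where the call ends (adjusted p = 0.0648), and -0.93 against it alone. Abemaciclib gave no call for them (adjusted p = 0.467).

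Several other lists in MCF-7 had calls with ribociclib and abemaciclib that an estimated correlation ends. MAPK and AP-1 genes fell at 12 of 24 members with each drug (medians -0.70 and -0.61, adjusted p = 0.00027 and 0.00021), with an estimated correlation adjusted p = 0.444 and adjusted p = 0.487. Their medians are -1.06 and -0.89 without vehicle replicate 1 and -0.08 and -0.06 against it alone. The p53 targets fell at 8 and 10 of 25 members (adjusted p = 0.00043 and 0.00038; estimated correlation, adjusted p = 0.468 and adjusted p = 0.506), and their medians of -0.34 and -0.26 become -0.47 and -0.39 without vehicle replicate 1 and 0.03 and 0.04 against it alone. Luminal genes were lower at 10 and 12 of 22 members (medians -0.26 and -0.28, adjusted p = 0.0019 and 0.0002; estimated correlation, adjusted p = 0.313 and adjusted p = 0.207). Without vehicle replicate 1 their medians are -0.31 and -0.44, and against it alone they are -0.105 and -0.10 and no longer called (adjusted p = 0.532 and 0.265). Estrogen-responsive genes were lower at 14 of 40 members with each drug (medians -0.16 and -0.17, adjusted p = 0.0075 and 0.00081; estimated correlation, adjusted p = 0.313 and adjusted p = 0.239). These medians are -0.24 and -0.29 without vehicle replicate 1, and -0.038 and -0.11 against it alone, where the calls end (adjusted p = 0.516 and 0.177).

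Aryl hydrocarbon receptor and drug handling genes were higher at 7 of 13 members in MCF-7 with ribociclib and with abemaciclib (medians 0.51 and 0.55, adjusted p = 0.0028 and 0.0026). With an estimated correlation adjusted p = 0.165 and adjusted p = 0.191, and without vehicle replicate 1 the list is not called (medians 0.58 and 0.55, adjusted p = 0.152 and 0.208), while against it alone the medians are 0.56 and 0.53. Ribosomal protein genes were lower at 10 and 13 of 21 members (13 each over the list alone; medians -0.23 and -0.29, adjusted p = 0.00026 and 8.1e-05; estimated correlation, adjusted p = 0.195 and adjusted p = 0.191). The ribosomal medians are -0.29 and -0.34 without vehicle replicate 1 and -0.15 and -0.10 against it alone. Lists without a call with palbociclib, ribociclib and abemaciclib in MCF-7 include the CDK4/6, cyclin and RB pathway (adjusted p = 0.106, 0.377 and 0.819), the interferon-stimulated genes (0.178, 0.932 and 0.431), and the fibroblast and leukocyte markers (0.326, 0.380 and 0.0859). With abemaciclib the marker list is called as higher in a fit of only the groups compared (adjusted p = 0.0288) and without abemaciclib replicate 3 (0.0438).

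The 3 drugs can be set beside each other only at these doses, which differ. In T47D ribociclib and palbociclib differed at 3071 genes, 1415 higher and 1656 lower with ribociclib. G1/S genes were higher with ribociclib at 61 of 65 members (63 over the list alone; median 0.74, adjusted p = 1.7e-51) and G2/M genes at 57 of 62 (median 0.77, adjusted p = 2.2e-48). FAM111B differed by 2.96 (SE 0.16), H2BC14 by 2.76 (SE 0.10), CCNE2 by 2.05 (SE 0.14) and MKI67 by 1.38 (SE 0.08, adjusted p = 4.2e-12). Abemaciclib and palbociclib differed at 787 T47D genes, 415 higher and 372 lower with abemaciclib, and the count is 402 and 505 without abemaciclib replicate 1 or 2, and 429 and 500 without palbociclib replicate 1 or 2. The G2/M genes were higher with abemaciclib at 47 members (54 over the list alone; median 0.52, adjusted p = 9.2e-54) and the G1/S genes were not called (adjusted p = 0.481). MKI67 differed by 0.83 (SE 0.08) and KIF2C, a mitotic kinesin, by 1.11 (SE 0.10), while E2F1 did not pass (-0.18, 95% interval -0.40 to 0.05, adjusted p = 0.434).

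Abemaciclib and ribociclib differed at 502 T47D genes, 240 higher and 262 lower with abemaciclib. Omitting abemaciclib replicate 2 or 3 leaves 271 and 288, omitting ribociclib replicate 2 or 3 leaves 282 and 309, and fitting only these 6 arrays leaves 320. G1/S genes were lower with abemaciclib at 55 of 65 members (60 over the list alone; median -0.65, adjusted p = 1.9e-95), and G2/M genes at 19 of 62 (37 over the list alone; median -0.22, adjusted p = 8.0e-21). CCNE2 differed by -2.57 (SE 0.14), DTL by -2.36 (SE 0.07), E2F1 by -1.33 (SE 0.11) and MKI67 by -0.55 (SE 0.08, adjusted p = 4.3e-05). ESR1 showed no difference between these drugs (0.03, 95% interval -0.12 to 0.19), and CDK6 showed none either (0.09, 95% interval -0.35 to 0.52).

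In MCF-7 the differences between drugs do not use the vehicle means, but the vehicle arrays enter the spread estimated for each gene. Ribociclib and palbociclib differed at 2786 genes, 1349 higher and 1437 lower with ribociclib (1681 without palbociclib replicate 1, 4559 when only these 6 arrays are fitted). G2/M genes were higher with ribociclib at 35 of 62 members (43 over the list alone; median 0.54, adjusted p = 1.5e-17) and G1/S genes at 13 of 65 (median 0.17, adjusted p = 0.00015). An estimated correlation ends both calls, adjusted p = 0.477 and 0.743. The aryl hydrocarbon receptor and drug handling genes were higher at 8 of 13 members (median 0.40, adjusted p = 3.5e-06), led by CYP1B1 (1.40, SE 0.23), CYP1A1 (1.30, SE 0.20) and ABCG2 (1.18, SE 0.06). IL24, a cytokine, was lower with ribociclib (-2.03, SE 0.29). MKI67 did not pass (0.36, 95% interval -0.05 to 0.78, adjusted p = 0.216), and is called when only the 6 arrays are fitted (adjusted p = 8.7e-05).

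Abemaciclib and palbociclib differed at 2023 MCF-7 genes, 979 higher and 1044 lower with abemaciclib (3221 when only these 6 arrays are fitted). The count is 1112, 1257 and 1340 without palbociclib replicate 1, 2 or 3, and 1218 and 1253 without abemaciclib replicate 2 or 3. G1/S genes were higher with abemaciclib at 51 of 65 members (57 over the list alone; median 0.63, adjusted p = 1.7e-32) and G2/M genes at 56 of 62 (59 over the list alone; median 0.88, adjusted p = 1.1e-40), with an estimated correlation adjusted p = 0.193 for each. Histones were higher at 9 of 11 members (median 1.00, adjusted p = 2.7e-12) and drug handling genes at 8 of 13 (median 0.38, adjusted p = 9.8e-07), and an estimated correlation keeps these 2 calls. H2BC14 differed by 2.44 (SE 0.07), CYP1A1 by 1.73 (SE 0.20), CCNE2 by 1.40 (SE 0.13) and MKI67 by 0.81 (SE 0.20, adjusted p = 0.0111).

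Abemaciclib and ribociclib differed at 24 MCF-7 genes, 19 higher and 5 lower with abemaciclib. The count is 13, 7 and 9 without abemaciclib replicate 1, 2 or 3, 11, 8 and 9 without ribociclib replicate 1, 2 or 3, and 400 when only these 6 arrays are fitted. H1-5 (1.54, SE 0.21), H1-4 (1.23, SE 0.10) and H2BC14 (1.11, SE 0.07), all histones, were higher with abemaciclib. G1/S genes were higher at 7 of 65 members over all genes and at 47 over the list alone (median 0.42, adjusted p = 4.3e-37), with an estimated correlation adjusted p = 0.343. No difference was called for CDK6 (-0.08, 95% interval -0.45 to 0.29) or for PGR (-0.13, 95% interval -0.77 to 0.52).

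Genes called in the same direction by several drugs of a line share its vehicle arrays. In T47D palbociclib and ribociclib shared 1780 higher and 1819 lower genes, where independent calls give 521 and 479.7. Palbociclib and abemaciclib shared 2056 and 2002 (independent 524.1 and 414.8), and ribociclib and abemaciclib 2288 and 2190 (independent 591 and 512.7). All 3 drugs shared 3405 genes, 1679 higher and 1726 lower. Unchanged groups simulated with shared vehicle arrays gave 0.1, 0 and 0.05 shared genes for the pairs. The covariance of the differences was 0.20, 0.236 and 0.219, against 0.0155, 0.0156 and 0.0157 in the simulation. Part of the excess may still come from the shared controls, since 3 vehicle arrays cannot be divided between drugs.

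In MCF-7 palbociclib and ribociclib shared 1047 higher and 513 lower genes (independent 321.5 and 117.6; simulated 123.35 in all). Palbociclib and abemaciclib shared 1103 and 542 (independent 307.3 and 116; simulated 123.3), and ribociclib and abemaciclib 1902 and 1372 (independent 439.8 and 234; simulated 123). All 3 shared 1375 genes, with 106.1 simulated, and 3843 without vehicle replicate 1 or 271 against it alone. The differences correlate at 0.65, 0.66 and 0.85, and unchanged groups that share vehicle arrays correlate at 0.70. Covariances are 0.0933, 0.0935 and 0.145 against 0.0383, 0.0383 and 0.0384 simulated, and the differing vehicle arrays enter every one of them. Across the lines no arrays are shared. Palbociclib moved 520 genes higher and 346 lower in each line (independent 320.2 and 149.8) and 371 in opposite directions. For ribociclib 315 and 270 were shared (independent 518.4 and 374.7) with 1688 opposite, and for abemaciclib 420 and 223 (independent 493.7 and 319.3) with 1443 opposite. Without MCF-7 vehicle replicate 1 the shared genes rise from 866 to 1284 for palbociclib, 585 to 1015 for ribociclib and 643 to 1054 for abemaciclib. The MCF-7 genes called rise as well, from 2752 to 5740, 4482 to 6376 and 4342 to 6490. Shared counts change with the number of genes called, so they do not measure agreement between the lines.

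The drug effects differed between the lines at 4028 genes for palbociclib, 6295 for ribociclib and 5815 for abemaciclib. The doses differ between the lines, and the MCF-7 side contains the differing vehicle arrays. With all of these arrays, G1/S and G2/M genes were higher with abemaciclib in MCF-7. A lower effect in T47D thus does not mean a fall in each line. G1/S genes were lower in T47D relative to MCF-7 at 65, 62 and 64 of 65 members (medians -1.99, -1.36 and -2.62, adjusted p = 1.1e-69, 4.5e-29 and 9.5e-64). The medians are -2.29, -1.61 and -2.85 without MCF-7 vehicle replicate 1 and -1.45, -0.90 and -2.07 against it alone. G2/M genes were lower in T47D relative to MCF-7 at all 62 members (medians -1.98, -1.63 and -2.20, adjusted p = 2.2e-54, 5.1e-31 and 6.7e-49), with medians of -2.32, -1.90 and -2.5 without that array and -1.25, -0.98 and -1.58 against it alone. With an estimated correlation ribociclib loses these calls, adjusted p = 0.129 for G1/S and 0.132 for G2/M. CCNE2 differed by -4.56, -3.24 and -6.49 (SE 0.20) and MKI67 by -2.52, -1.5 and -2.5 (SE 0.22), with -0.71 for ribociclib against that array alone. Luminal genes were higher in T47D relative to MCF-7 at 7, 16 and 15 of 23 members (medians 0.31, 0.59 and 0.51, adjusted p = 0.00084, 0.00025 and 2.3e-05). An estimated correlation gives adjusted p = 0.0706 and 0.129 for the first 2. The luminal medians are 0.43, 0.54 and 0.61 without MCF-7 vehicle replicate 1, and 0.0054, 0.27 and 0.47 against it alone, where the palbociclib call ends (adjusted p = 0.104).

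**Figure D3:**
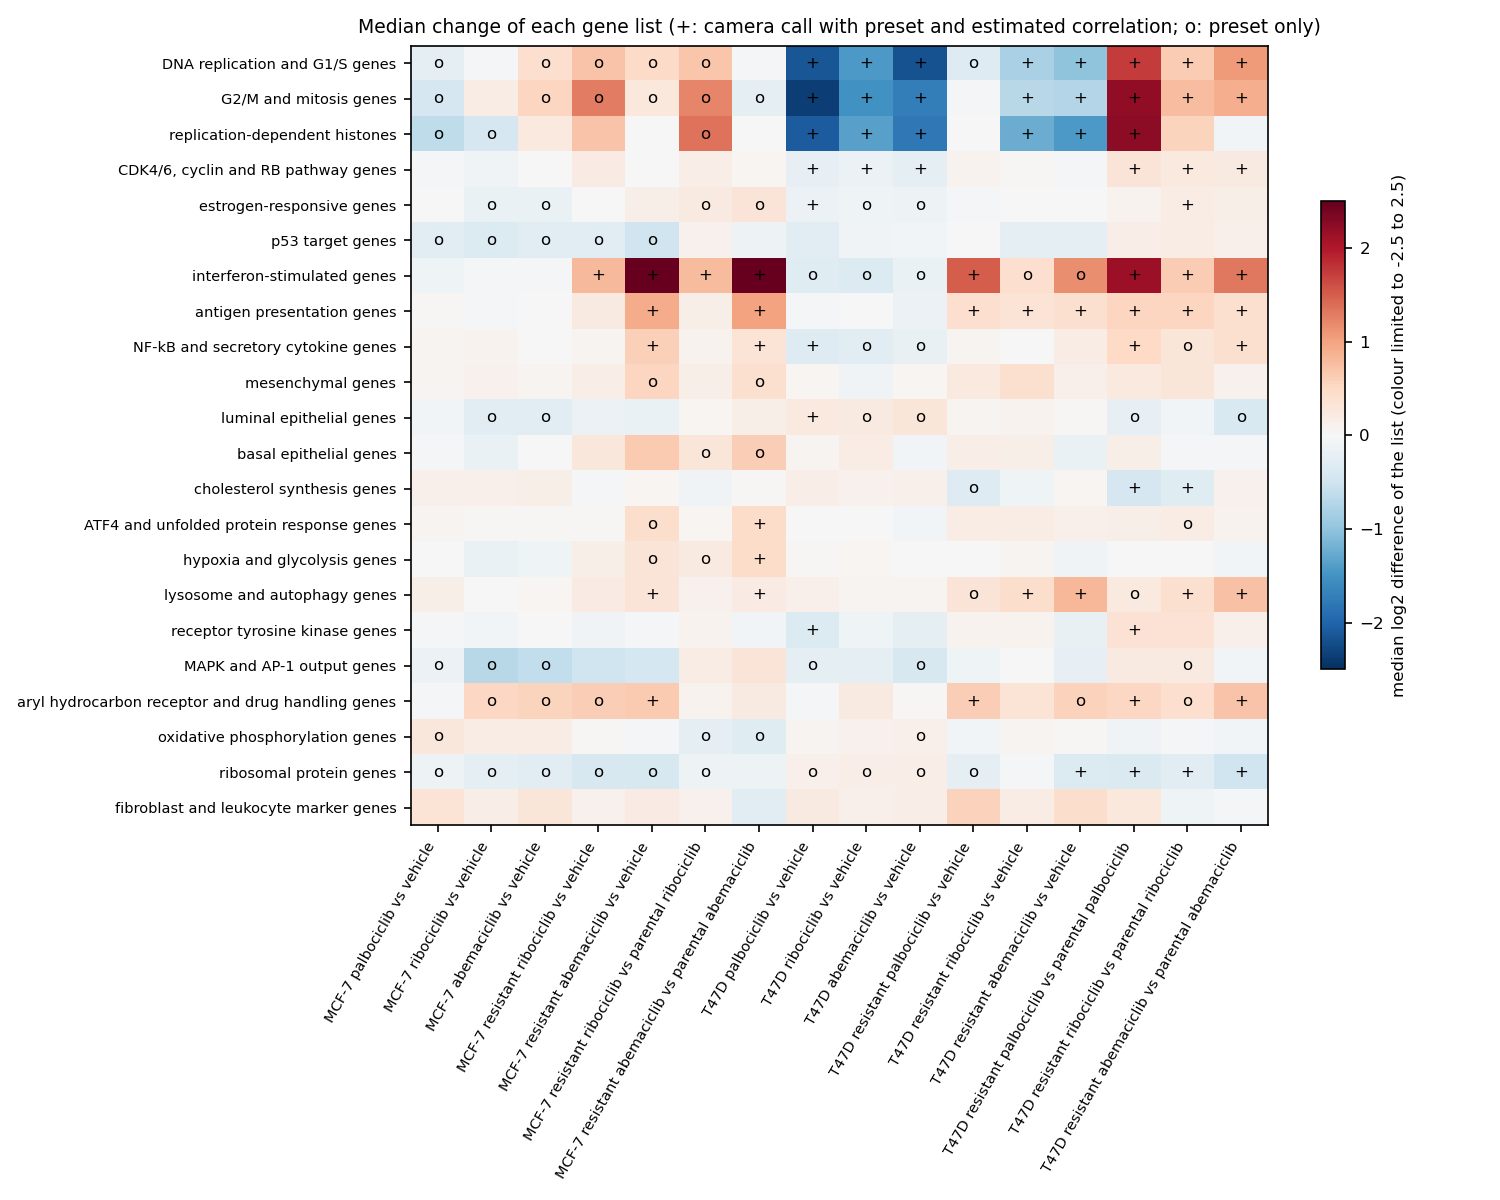
Median log2 difference of the gene lists in the comparisons.

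Resistant T47D cells were set beside parental T47D cells in the same drug. Resistant palbociclib cells had 7461 genes called, 3419 higher and 4042 lower, with 1014 at least 2-fold higher. TFAP2B, a luminal developmental factor, rose from 2.94 (SD 0.15) to 9.16 (SD 0.09, adjusted p = 5.0e-19), and IFI44, an interferon-induced gene, from 2.94 (SD 0.33) to 8.74 (SD 0.19). LUM, the matrix proteoglycan lumican, rose by 5.31 (SE 0.24) and IFI27 by 4.66 (SE 0.20). CDH10, a neural cadherin, fell by 7.04 (SE 0.21) and TPM4, a tropomyosin, by 4.62 (SE 0.13) on the log2 scale. MCM10 was higher by 4.07 (SE 0.08), CCNE2 by 3.93 (SE 0.14), MKI67 by 3.06 (SE 0.08) and E2F1 by 3.02 (SE 0.11). CDK6 rose 6.73-fold from 4.44 (SD 0.28) to 7.19 (SD 0.28, adjusted p = 6.5e-11).

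Resistant ribociclib T47D cells had 5699 genes called, 2725 higher and 2974 lower. SLC6A14, an amino acid transporter, rose from 2.88 (SD 0.34) to 9.45 (SD 0.08, adjusted p = 3.0e-17). CYP4X1 rose by 5.55 (SE 0.16) and LUM by 5.48 (SE 0.24), and CDH10 fell by 4.26 (SE 0.21) and ALDH2, the mitochondrial aldehyde dehydrogenase, by 4.18 (SE 0.22) on the log2 scale. CDK6 rose 4.75-fold from 4.53 (SD 0.30) to 6.78 (SD 0.04, adjusted p = 6.4e-09), and CCND1, its partner cyclin D1, by 0.82 (SE 0.09). Of 40 estrogen-responsive genes 19 were higher and 5 lower (median 0.19, adjusted p = 0.00012), among them PDZK1 (2.74, SE 0.25). The list mean was 8.31, against 7.93 in parental cells in drug and 8.28 with vehicle. MKI67 rose by 0.74 (SE 0.08) and CCNE2 by 1.10 (SE 0.14).

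Resistant abemaciclib T47D cells had 7302 genes called, 3509 higher and 3793 lower. CLEC3A, a secreted lectin, rose by 7.81 (SE 0.20, adjusted p = 2.1e-19), LUM by 6.39 (SE 0.24) and GJA1, the gap junction protein connexin 43, by 6.15 (SE 0.19). LRRN3, a leucine-rich repeat membrane protein, fell by 5.69 (SE 0.14), CDH10 fell by 5.28 (SE 0.21) and TBX18 fell by 5.14 (SE 0.14) on the log2 scale. CDK6 rose 7.25-fold from 4.62 (SD 0.55) to 7.47 (SD 0.10, adjusted p = 3.3e-11). Lysosome and autophagy genes were higher at 21 of 25 members (median 0.72, adjusted p = 8.5e-10), with GPNMB, a lysosomal stress glycoprotein, at 3.41 (SE 0.12), GLA, a lysosomal galactosidase, at 2.07 (SE 0.07) and MCOLN1, a lysosomal calcium channel, at 1.77 (SE 0.10).

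In drug, proliferation genes were higher in resistant than in parental T47D cells. G1/S genes were higher at 63, 51 and 56 of 65 members in the palbociclib, ribociclib and abemaciclib lines (63, 56 and 56 over the list alone; medians 1.76, 0.64 and 1.07, adjusted p = 4.8e-43, 3.7e-21 and 7.7e-25). G2/M genes were higher at 62, 60 and 57 of 62 (medians 2.21, 0.77 and 0.90, adjusted p = 5.5e-49, 1.2e-29 and 6.8e-24). Pathway genes of CDK4/6, cyclins and RB were higher at 16, 12 and 13 of 28 (adjusted p = 0.00023, 0.00039 and 0.0034). CCNE1 rose by 2.74, 1.56 and 2.76 (SE 0.12). Histones were higher at 9 of 11 members in the palbociclib line (adjusted p = 2.2e-06) and not called in the others (adjusted p = 0.105 and 0.390). ESR1 fell by 0.59, 0.47 and 0.38 on the log2 scale (SE 0.08).

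Interferon-stimulated genes were higher at 38, 29 and 35 of 40 members in the same 3 resistant T47D lines (medians 2.14, 0.64 and 1.32, adjusted p = 2.1e-23, 3.3e-11 and 7.0e-16). Antigen presentation genes were higher at 14, 14 and 13 of 23 (adjusted p = 0.00015, 9.2e-06 and 0.0027), and HLA-DRA, a class II antigen chain, rose by 3.25, 1.52 and 3.22 (SE 0.27). NF-kB and secretory cytokine genes were higher at 8, 5 and 6 of 12 (adjusted p = 0.0066, 0.0396 and 0.009). The ribociclib call ends with an estimated correlation (adjusted p = 0.0714), with no filter (0.109), without ribociclib replicate 1 (0.0843) and without resistant replicate 3 (0.0661). In the palbociclib and abemaciclib lines CCL2, a monocyte attractant, rose by 3.07 and 2.43 (SE 0.35). Fibroblast and leukocyte markers were not called (adjusted p = 0.0919, 0.512 and 0.335), although LUM belongs to that list.

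**Figure D4:**
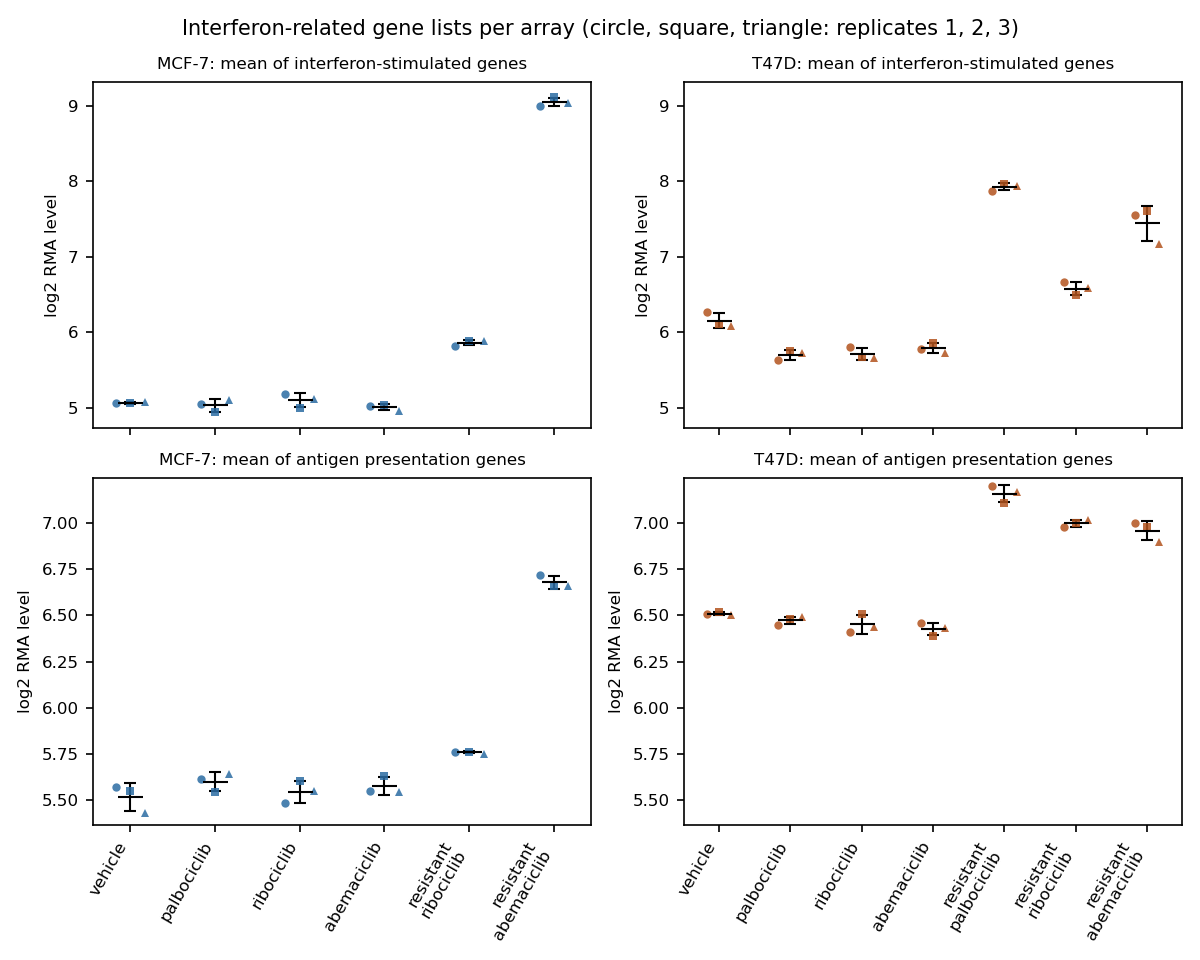
Mean log2 level per array of the interferon-stimulated and antigen presentation genes in the 13 groups. Points are arrays, bars are the mean with SD, n = 3.

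Metabolic lists moved in resistant T47D cells as well. Ribosomal protein genes were lower at 15, 14 and 20 of 21 members (medians -0.36, -0.26 and -0.49, adjusted p = 0.00039, 9.4e-05 and 4.0e-08), with RPL37, a large subunit protein, at -1.23 (SE 0.09) in the palbociclib line. Cholesterol synthesis genes were lower at 13 and 11 of 19 in the palbociclib and ribociclib lines (medians -0.42 and -0.30, adjusted p = 0.00082 and 3.0e-05) and not called in the abemaciclib line (adjusted p = 0.880). HMGCS1, an early enzyme of that route, fell by 1.12 (SE 0.07) on the log2 scale in the palbociclib line. Lysosome genes were higher at 17 of 25 in the ribociclib line (median 0.39, adjusted p = 1.3e-06) and at 13 in the palbociclib line (adjusted p = 0.0074; estimated correlation, adjusted p = 0.158). Drug handling genes were higher at 9, 6 and 9 of 14 (adjusted p = 0.0028, 0.0396 and 0.0097), with ABCC2, an efflux pump, at 2.64 (SE 0.21) in the palbociclib line. Their ribociclib call ends with an estimated correlation (adjusted p = 0.0615), with no filter (0.0942) and without ribociclib replicate 1 (0.0538). Receptor tyrosine kinases were higher at 10 of 17 in the palbociclib line (adjusted p = 0.0268), and RET, a growth factor receptor, rose by 2.07, 1.77 and 1.95 (SE 0.29) across the 3 lines. Luminal genes were lower at 11 and 14 of 23 in the palbociclib and abemaciclib lines (adjusted p = 0.0394 and 0.0139; estimated correlation, adjusted p = 0.120 and adjusted p = 0.0668). The palbociclib call also ends with quantile normalization (0.0677), in a fit of only the 6 arrays (0.0539), without palbociclib replicate 2 (0.0526) and without resistant replicate 1 or 3 (0.0506 and 0.0502). Mesenchymal genes were not called (adjusted p = 0.308, 0.0909 and 0.688), and CD44, an adhesion receptor on that list, fell by 1.89, 2.21 and 2.62 (SE 0.09) on the log2 scale.

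Against vehicle, resistant T47D cells in drug had 6493, 6783 and 7508 genes called in the palbociclib, ribociclib and abemaciclib lines (2905, 3202 and 3635 higher). After quantile normalization higher genes become the majority in the palbociclib and ribociclib lines. G1/S genes stayed below vehicle at 41, 59 and 63 of 65 members (medians -0.32, -0.80 and -1.01, adjusted p = 1.5e-06, 1.5e-23 and 4.0e-26). With an estimated correlation the palbociclib line loses that call, adjusted p = 0.0842. G2/M genes were lower at 58 and 62 of 62 in the ribociclib and abemaciclib lines (medians -0.69 and -0.73, adjusted p = 1.4e-21 and 5.1e-20), while the palbociclib line gave 11 higher and 16 lower (adjusted p = 0.795). MKI67 was not called in that line (0.14, SE 0.08, adjusted p = 0.154, but 0.0129 after quantile normalization and 0.0307 in a fit of only the 6 arrays) and changed by -0.81 and -0.86 (SE 0.08) in the others. CCNE2 fell by 0.96, 1.74 and 2.01 (SE 0.14) and RB1 by 0.73, 0.78 and 0.83 (SE 0.08) on the log2 scale, and CDK6 rose by 2.59, 2.18 and 2.88 (SE 0.21).

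The largest rises of the resistant T47D lines over vehicle were TFAP2B in the palbociclib line (5.84, SE 0.18), GUCY1A1, a nitric oxide receptor subunit, in the ribociclib line (5.51, SE 0.29) and CLEC3A in the abemaciclib line (7.17, SE 0.20). LUM rose by 5.54, 4.77 and 6.15 (SE 0.24). TPM4 fell by 3.65, 3.35 and 4.17 (SE 0.13) on the log2 scale. Interferon-stimulated genes were higher at 36, 20 and 34 of 40 members (medians 1.52, 0.42 and 1.16, adjusted p = 3.3e-24, 0.0021 and 1.8e-11), and with an estimated correlation only the palbociclib line keeps the call, adjusted p = 0.393 and adjusted p = 0.0541 for the others. Antigen presentation genes were higher at 12, 12 and 13 of 23 (adjusted p = 3.6e-06, 0.00035 and 0.0047). Lysosome genes were higher at 12, 17 and 23 of 25 (medians 0.32, 0.44 and 0.83, adjusted p = 0.00022, 4.1e-06 and 1.7e-11), and with an estimated correlation adjusted p = 0.0842 for the palbociclib line.

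Resistant ribociclib MCF-7 cells had 3581 genes called against parental MCF-7 cells in ribociclib, 1897 higher and 1684 lower. SLC6A14 rose from 3.48 (SD 0.39) to 10.46 (SD 0.07, adjusted p = 1.7e-09), PEG10, a retrotransposon-derived gene, by 4.05 (SE 0.19) and STEAP4, a metalloreductase, by 4.03 (SE 0.23). PDCL2, a phosducin-like protein, fell by 6.15 (SE 0.15), and ERBB4, a growth factor receptor, and MME, the surface peptidase CD10, fell by 2.94 (SE 0.28) and 2.65 (SE 0.16) on the log2 scale. G1/S genes were higher at 52 of 65 members (57 over the list alone; median 0.69, adjusted p = 4.9e-22) and G2/M genes at 60 of 62 (62 over the list alone; median 1.22, adjusted p = 9.8e-34). With an estimated correlation these give adjusted p = 0.216 and 0.194. Interferon-stimulated genes were higher at 27 of 39 (median 0.79, adjusted p = 1.5e-11), among them IFI6 (2.61, SE 0.17) and IFIH1, a sensor of double-stranded RNA (2.23, SE 0.15). MKI67 rose by 1.26 (SE 0.20), E2F1 by 1.29 (SE 0.21), CCNE2 by 0.98 (SE 0.13), CDK6 by 0.72 (SE 0.17) and PGR by 2.30 (SE 0.31), and ESR1 fell by 0.36 (SE 0.09) on the log2 scale.

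Resistant abemaciclib MCF-7 cells had 4710 genes called against parental MCF-7 cells in abemaciclib, 2184 higher and 2526 lower. SLC6A14 rose from 3.13 (SD 0.14) to 10.84 (SD 0.02, adjusted p = 6.4e-11). Interferon-stimulated genes were higher at 38 of 39 members (39 over the list alone; median 4.03, adjusted p = 1.1e-56). IFI44 went from 2.18 (SD 0.24) to 9.44 (SD 0.05), OAS2, an RNA-sensing synthetase, rose by 7.35 (SE 0.30) and XAF1, a proapoptotic interferon target, by 7.0 (SE 0.15). Antigen presentation genes were higher at 14 of 23 (median 1.01, adjusted p = 3.7e-11), with HLA-DRA at 3.44 (SE 0.21) and TAP1, a peptide transporter, at 2.54 (SE 0.14). RB1 fell 3.92-fold, from 9.63 (SD 0.07) to 7.66 (SD 0.01, adjusted p = 1.5e-12). PGR rose by 3.5 (SE 0.31) and CD44 by 3.86 (SE 0.24), and PDCL2 fell by 6.09 (SE 0.15) and MME by 4.15 (SE 0.16) on the log2 scale.

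**Figure D5:**
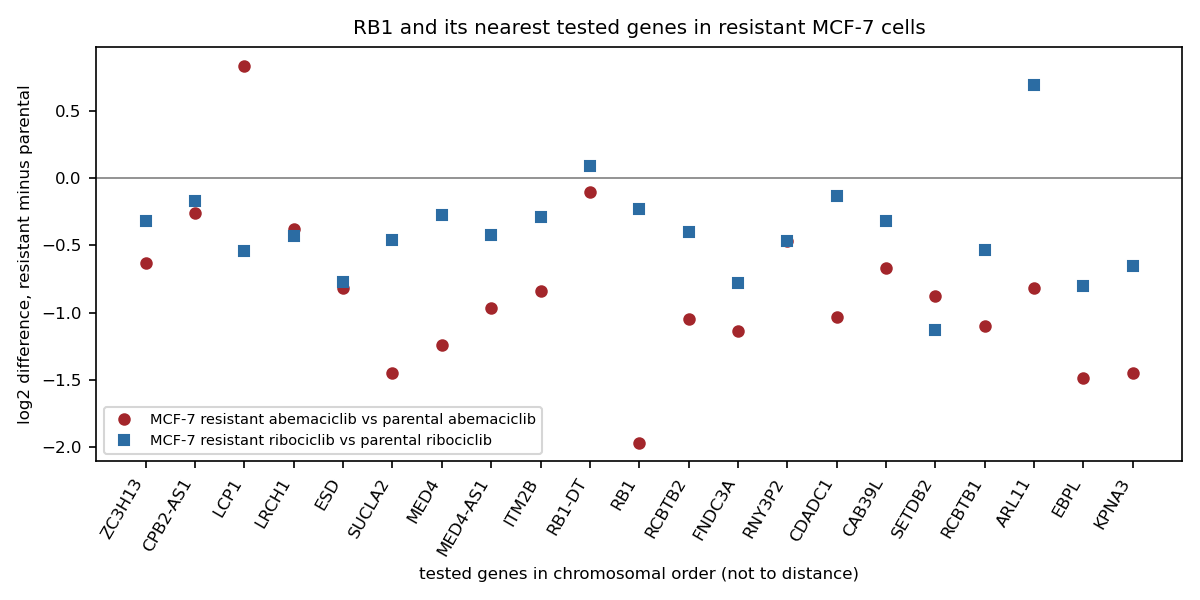
Log2 difference of RB1 and of its neighbours on the chromosome in resistant MCF-7 cells against parental cells in the same drug.

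Proliferation lists in the resistant abemaciclib MCF-7 line did not rise over parental cells in drug. G1/S genes gave 9 higher and 6 lower of 65 (adjusted p = 0.669). G2/M genes gave 13 lower of 62 (median -0.23, adjusted p = 0.0474), with 0.109 and 0.0615 without abemaciclib replicate 2 or 3 and 0.0794 and 0.0613 without resistant replicate 1 or 2. With an estimated correlation that list gives adjusted p = 0.843, and MKI67 was not called (-0.35, SE 0.20, adjusted p = 0.199), but is called when only the 6 arrays are fitted (adjusted p = 0.00076). Stress lists were higher: ATF4 and unfolded protein response at 16 of 27 members (median 0.46, adjusted p = 2.6e-06), hypoxia and glycolysis at 12 of 23 (15 over the list alone; median 0.45, adjusted p = 1.1e-06), lysosome and autophagy at 9 of 24 (adjusted p = 0.00079) and NF-kB and cytokines at 7 of 13 (adjusted p = 0.0036). SLC7A11, the cystine importer, rose by 1.13 (SE 0.11), DDIT3, a stress transcription factor, by 1.45 (SE 0.19) and HK2, a glycolytic hexokinase, by 1.56 (SE 0.13). Estrogen-responsive genes were higher at 20 of 40 (adjusted p = 0.00079; estimated correlation, adjusted p = 0.114), with CXCL12, a chemokine, at 4.59 (SE 0.28). Basal epithelial genes were higher at 7 of 12 (adjusted p = 0.0038; estimated correlation, adjusted p = 0.0827) and mesenchymal genes at 8 of 17 (adjusted p = 0.0154; estimated correlation, adjusted p = 0.203). Oxidative phosphorylation genes were lower at 9 of 21 (adjusted p = 0.0068; estimated correlation, adjusted p = 0.457).

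Against MCF-7 vehicle the resistant ribociclib and abemaciclib lines had 5721 and 6062 genes called (3306 and 3145 higher). The counts are 7109 and 7217 without vehicle replicate 1, and 3280 and 3579 when only the 6 arrays compared are fitted. Interferon-stimulated genes were higher at 28 and 38 of 39 members (medians 0.80 and 3.75, adjusted p = 5.0e-08 and 4.3e-43), with medians of 0.75 and 3.61 without vehicle replicate 1 and 0.62 and 3.93 against it alone. G2/M genes were higher at all 62 members in the ribociclib line (median 1.28, adjusted p = 1.4e-25; estimated correlation, adjusted p = 0.331), and their median is 1.63 without vehicle replicate 1 and 0.66 against it alone. In the abemaciclib line their median is 0.26 (20 higher, adjusted p = 0.0111; estimated correlation, adjusted p = 0.693) with 0.63 without vehicle replicate 1 and -0.35 against it alone. Its G1/S median of 0.48 (adjusted p = 9.6e-06; estimated correlation, adjusted p = 0.621) is 0.71 and -0.09 under the same changes. Ribosomal protein genes were lower at 16 and 15 of 21 (medians -0.41 and -0.41, adjusted p = 5.7e-07 and 3.8e-05; estimated correlation, adjusted p = 0.0649 and adjusted p = 0.0566), with -0.41 and -0.53 without vehicle replicate 1 and -0.25 and -0.21 against it alone. ABCG2 rose by 2.21 (SE 0.06) in the ribociclib line, CDK6 by 1.16 and 0.90 (SE 0.17) and CCNE2 by 1.37 and 1.65 (SE 0.13) in the 2 lines. RB1 was not called in the ribociclib line (0.05, SE 0.08, adjusted p = 0.662, but 0.0398 without vehicle replicate 1) and fell by 1.79 (SE 0.08, adjusted p = 4.0e-12) on the log2 scale in the abemaciclib line.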

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

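In this part 3 tests on the MCF-7 vehicle arrays, against other analysed MCF-7 groups, against the palbociclib group and against the 2 resistant lines, the results with MCF-7 vehicle replicate 1 alone, the gene list results with a replicate omitted or with only the groups compared in the fit, and the number and the sorting of the splits for effect differences were chosen only after results were seen. The results listed first are differences between the lines in the effect of a drug, tested as interaction terms in limma. Drug doses differ between the lines, so dose and line cannot be separated here. The MCF-7 vehicle arrays enter each of these values.

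The counts are 4028 genes for palbociclib, 6295 for ribociclib and 5815 for abemaciclib. For palbociclib 60 splits of the arrays were drawn first, and 3 gave at least 4028 genes, a share of 0.05. The number was raised to 100 after that was seen, and 4 of the 100 gave as many, a share of 0.04, with 4201 the highest of the others. For ribociclib and abemaciclib the real split gave the largest count of the 100 drawn, with 4836 and 4687 the highest others. These shares do not test the difference between the lines, because 90 of the 100 splits mix T47D arrays and so remove the T47D drug effect, and these gave at most 1156, 2754 and 2446 genes for palbociclib, ribociclib and abemaciclib. The other 9 leave the T47D groups whole or exchange them entirely and mix only MCF-7 arrays, and they gave 2099 to 4201, 2437 to 4836 and 2404 to 4687 genes. Beside these 9 the real count is the largest for ribociclib and abemaciclib but not for palbociclib, and 10 splits are too few for a share under 0.05. These 9 also keep the T47D drug effect, so they call many genes whether or not the lines differ. The splits therefore cannot decide on chance for any of the 3 drugs.

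For palbociclib the list medians, T47D minus MCF-7, were -1.99 for G1/S, -1.98 for G2/M, -1.03 for histones, -0.13 for the CDK4/6 pathway, -0.24 for interferon-stimulated and -0.34 for NF-kB genes. They were 0.17 for p53 targets, 0.31 for luminal and 0.20 for ribosomal protein genes. For ribociclib they were -1.36 for G1/S, -1.63 for G2/M, -0.39 for interferon-stimulated, 0.59 for luminal and 0.39 for ribosomal protein genes. For abemaciclib they were -2.62 for G1/S, -2.20 for G2/M, -1.44 for histones, -0.25 for the CDK4/6 pathway, 0.51 for luminal and 0.42 for ribosomal protein genes. The interferon-stimulated list has adjusted p = 0.0721 for palbociclib and 0.061 for ribociclib without T47D vehicle replicate 1, and for palbociclib 0.0591 without T47D palbociclib replicate 1 and 0.0524 without MCF-7 palbociclib replicate 3. For palbociclib the p53 targets have adjusted p = 0.0979 in a fit of only the groups compared and a median of -0.18 against MCF-7 vehicle replicate 1 alone. The NF-kB genes have adjusted p = 0.222 with no filter, and the luminal genes adjusted p = 0.104 against that array alone. Without MCF-7 vehicle replicate 1 the CDK4/6 pathway has adjusted p = 0.0602 for palbociclib and 0.0598 for abemaciclib, the interferon-stimulated list 0.194 for palbociclib and 0.0853 for ribociclib, and the NF-kB list 0.295 for palbociclib, while the palbociclib p53 call ends without MCF-7 vehicle replicate 2 or 3 (0.0986 and 0.185). An estimated correlation ends the palbociclib calls of histones (adjusted p = 0.0511), p53 targets (0.508), interferon-stimulated (0.508), NF-kB (0.0849), luminal and ribosomal protein genes (0.0706 each). It also ends all 5 ribociclib calls (G1/S 0.129, G2/M 0.132, interferon-stimulated 0.491, luminal and ribosomal 0.129 each).

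Among single genes palbociclib gave FAM111B -5.03, CCNE2 -4.56, MCM10 -4.17, MKI67 -2.52, CCNE1 -2.52, E2F1 -2.37, PGR 1.76 and TBX18 3.25. Ribociclib gave H2AC14 -3.51, CYP4X1 -3.40, CCNE2 -3.24, MKI67 -1.50, PGR 1.87, TBX18 3.08 and FOS 3.21. Abemaciclib gave CCNE2 -6.49, FAM111B -6.41, H2BC14 -5.21, E2F1 -3.23, MKI67 -2.5, PGR 2.04, FZD6 3.14 and TBX18 3.30. Against MCF-7 vehicle replicate 1 alone FOS is 0.34 and no longer called, PGR is 0.60, 0.72 and 0.89 for palbociclib, ribociclib and abemaciclib, and for ribociclib MKI67 is -0.71 and H2AC14 -2.08.

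MCF-7 vehicle replicate 1 lies apart from replicates 2 and 3, with 804 of 14795 genes more than 1 apart on the log2 scale. Scaling that differs with level is argued against, since a smooth curve on the mean level explains 0.1945% of the variance of the difference, and mixing with T47D cells as well, with a median of -0.06 over 100 genes high in T47D (quartiles -0.48 and 0.23). An origin of replicates 2 and 3 in another analysed MCF-7 group is argued against by a highest mean correlation of 0.9725, below the 0.9896 that is the lowest within the other groups, and an origin of replicate 1 in the palbociclib group by a G1/S mean 0.71 outside the range of those arrays. An origin of replicates 2 and 3 in either resistant MCF-7 line of the series is argued against as well, since over 50 genes changed in these lines the ribociclib and abemaciclib lines lie a median of 2.30 (quartiles 1.53 and 2.80) and 2.69 (1.87 and 4.30) further than these replicates do, while an origin in other resistant cells cannot be told apart, because the replicates moved a median of 0.54 that way (0.23 and 1.24) and no other resistant MCF-7 cells were measured. A sample from outside the series or a different growth state of the culture may also be the cause and was not tested.

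The 22 comparisons of 3 arrays with 3 allow 10 splits, too few for a share under 0.05, and in each 1 split, the real one, gave the most genes. Every other split mixes the 2 groups compared, which shrinks their difference and widens the spread. Low counts of the other splits thus follow from the design and test nothing. The real counts and the highest of the other splits against MCF-7 vehicle were 2752 and 1461 for palbociclib, 4482 and 683 for ribociclib, 4342 and 1251 for abemaciclib, 5721 and 0 for the resistant ribociclib line, and 6062 and 1 for the resistant abemaciclib line. Against T47D vehicle they were 5065 and 1, 5974 and 0, and 5587 and 0 for palbociclib, ribociclib and abemaciclib, and 6493 and 1, 6783 and 0, and 7508 and 2 for the lines resistant to them. For resistant against parental cells they were 3581 and 0 (ribociclib) and 4710 and 1 (abemaciclib) in MCF-7, and 7461, 5699 and 7302, each with 0, in T47D. For drug against drug they were 2786, 2023 and 24 in MCF-7 with 0 each, and in T47D 3071 and 1, 787 and 0, and 502 and 0.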

How the results depend on the processing

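MCF-7 vehicle replicate 1 as the only MCF-7 vehicle array, omission of replicates and the fit of only the groups compared for gene lists, the alternatives for shared genes, and the look at medians that turn were chosen only after the data were seen. Where omission leaves a group with fewer arrays, the lone or remaining arrays are assumed to vary like the other groups. Quantile normalization and the mean of all probe sets moved none of the 38 counts by more than 1.5 times. Quantile normalization did shift the share of higher genes among those called from 44.74 to 57% for resistant palbociclib T47D cells against vehicle, from 47.21 to 57.99% for the resistant ribociclib cells, and from 47.81 to 32.27% for abemaciclib against ribociclib in T47D. No filter moved 1 count, abemaciclib against ribociclib in MCF-7, from 24 to 14, and the replicate number as a block moved the same count to 10. The replicate numbers do not pair arrays: residuals of arrays with the same number correlate at a mean of -0.002 in MCF-7 and -0.006 in T47D.

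A fit of only the groups compared moved 10 of 25 counts. In MCF-7 against vehicle it gave 7 for palbociclib, 1564 for ribociclib, 612 for abemaciclib, and 3280 and 3579 for the resistant ribociclib and abemaciclib lines. Between drugs in MCF-7 it gave 4559 for ribociclib against palbociclib, 3221 for abemaciclib against palbociclib and 400 for abemaciclib against ribociclib. It gave 320 for abemaciclib against ribociclib in T47D and 2443 for the palbociclib effect difference. This fit estimates the spread from fewer arrays, and in MCF-7 against vehicle the differing vehicle arrays then carry more of it.

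With MCF-7 vehicle replicate 1 alone the counts were 775 for palbociclib, 2890 for ribociclib, 1615 for abemaciclib and 1909 for the palbociclib effect difference. Genes shared by MCF-7 drugs were 500 for palbociclib and ribociclib, 290 for palbociclib and abemaciclib, 1355 for ribociclib and abemaciclib and 271 for all 3, and genes shared by the lines were 526 for palbociclib and 306 for abemaciclib. Without that array the shared genes were 4107, 4335, 5343 and 3843 between drugs, and 1284, 1015 and 1054 between lines for palbociclib, ribociclib and abemaciclib. Each is a change of the control arrays alone. Shared counts change with the number of genes called, so they do not measure agreement between drugs or lines.

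Omission of 1 replicate gave these ranges of counts in MCF-7. Against vehicle they were 986 to 5740 for palbociclib, 3309 to 6376 for ribociclib, 2818 to 6490 for abemaciclib, 4696 to 7109 for resistant ribociclib and 5222 to 7217 for resistant abemaciclib cells, the highest always without vehicle replicate 1. Against parental cells they were 2785 to 2918 and 3856 to 3985. Between drugs they were 1681 to 2111 for ribociclib against palbociclib, 1112 to 1503 for abemaciclib against palbociclib and 7 to 13 for abemaciclib against ribociclib. Effect differences ranged from 3103 to 5652, 5786 to 6876 and 5218 to 6656 for palbociclib, ribociclib and abemaciclib.

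In T47D the ranges against vehicle were 4388 to 4519, 5186 to 5414 and 4860 to 5021 for palbociclib, ribociclib and abemaciclib, and 5764 to 6018, 6024 to 6273 and 6824 to 6998 for the lines resistant to them. Against parental cells they were 6877 to 7046, 4957 to 5185 and 6654 to 6785. Between drugs they were 2311 to 2653 for ribociclib against palbociclib, 402 to 642 for abemaciclib against palbociclib and 271 to 431 for abemaciclib against ribociclib. Of 175 counts with 1 replicate omitted 33 moved by more than 1.5 times.

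Directions reversed in 28 cases, all against MCF-7 vehicle or in an effect difference built on it, counted where the result was called on at least 1 side. For lists the direction is that of the camera test, which follows the mean over members, so the median can keep its sign. Without vehicle replicate 1, ribociclib gave MKI67 0.35 (range over omissions -0.25 to 0.35) and the G1/S median 0.21. With replicate 1 alone palbociclib gave FOS 0.62, JUN 0.33, CCN2 0.45, CAV1 0.14, luminal genes 0.10 and MAPK and AP-1 genes 0.29. Ribociclib gave GDF15 0.12, CCN2 0.27, G2/M -0.47 and p53 targets 0.030. Abemaciclib gave MKI67 -0.39, GDF15 0.045, CCN2 0.35, G1/S -0.078, G2/M -0.11 and p53 targets 0.045. Resistant cells gave p53 targets 0.20 (ribociclib), and MKI67 -0.73, G1/S -0.094, G2/M -0.35 and MAPK and AP-1 genes 0.14 (abemaciclib), and the palbociclib effect difference gave p53 targets -0.18 and MAPK and AP-1 genes -0.51. In 3 of the 28 the median keeps its sign with replicate 1 alone: palbociclib estrogen-responsive genes (0.0098 and then 0.13) and ribosomal protein genes (-0.14 and -0.014), and abemaciclib MAPK and AP-1 genes (-0.61 and -0.063). In 7 further list results the median turns and the test direction does not, among them palbociclib G1/S, from -0.23 to 0.037 without vehicle replicate 1, and palbociclib p53 targets, from -0.29 to 0.0075 with it alone. Why replicate 1 differs stays open, and beyond the choice of vehicle array the cause was not tested.

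Of 444 results for single genes the fit of only the groups compared left 399 the same in direction and call, with 42 no longer called and 3 newly called. Quantile normalization left 442, the block 438, no filter 437 and the mean of probe sets 443. Omission of replicates left 2689 of 2802, with 96 no longer called and 16 newly called. Of 550 list results an estimated correlation left 447 and ended 103 calls. Quantile normalization left 541, no filter 528, the fit of only the groups compared 535, the mean of probe sets 548 and the block 550. Omission of replicates left 3579 of 3696, with 63 calls ended and 53 gained. Signal over background limits genes near the floor of 3.503, where RMA compresses differences, and without detection calls the genes below background cannot be marked.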

Other observations

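The genes shared by the resistant lines, the region around RB1 in the ribociclib-resistant cells, the other windows and single neighbours were looked at only after results were seen, while the tests on the median of 20 neighbours of RB1 in the abemaciclib-resistant cells and of CDK6 were written before. Against parental cells in the same drug, 417 genes were called in the same direction in all 5 resistant lines, 202 higher and 215 lower, where independent calls give 2.5 and 4. In the order MCF-7 ribociclib and abemaciclib, then T47D palbociclib, ribociclib and abemaciclib, SLC6A14 rose by 6.98, 7.71, 2.16, 6.57 and 1.99. In the palbociclib and abemaciclib lines of T47D it lay at 5.96 and 5.39, near the 5.23 of vehicle, and parental cells in drug lay at 3.80 and 3.40. SAMD9, an antiviral protein, rose by 1.66, 5.53, 3.44, 2.09 and 2.68, and OAS2 by 2.06, 7.35, 3.67, 1.35 and 2.61. APOD, a lipid carrier, rose by 1.45, 3.44, 2.45, 2.96 and 2.14, and PDZK1 by 1.64, 2.00, 1.99, 2.74 and 2.89. PDZK1 fell in parental T47D cells in drug, and the resistant T47D lines differed from vehicle by only -0.42, 0.07 and 0.43, with no call. TMPRSS2, a membrane protease, rose by 1.45, 1.60, 1.30, 1.67 and 1.55.

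Genes lower in all 5 lines include DOCK10, an activator of Rho-family GTPases, at -1.79, -1.94, -1.17, -1.04 and -0.98, and PNPLA4, a lipase, at -0.93, -1.20, -1.57, -1.34 and -1.17. IFITM2, an antiviral membrane protein, was at -1.78, -0.84, -1.02, -0.96 and -1.28, unlike the interferon-stimulated genes above. Resistant lines of T47D shared 3063 genes in all 3, 1455 higher and 1608 lower (independent 143 and 199.5), and those of MCF-7 shared 867 higher and 990 lower (independent 280 and 287.5) with 139 opposite. The resistant lines were set beside different parental arrays, so no control array is shared between these comparisons. Resistant and parental cells also differ in culture history, which the design does not separate from resistance.

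RB1 fell by 1.97 on the log2 scale in the abemaciclib-resistant MCF-7 cells against parental cells in abemaciclib. Loss of a region around RB1 is a candidate explanation: the 10 nearest tested genes on each side had a median of -0.86, with 16 of 20 lower and 1 higher, although RB1-DT, the nearest on one side, was at -0.10 and not called (adjusted p = 0.799). Of 14139 windows of that size 113 lay at or below -0.5, and the lowest was -1.31. In the ribociclib-resistant MCF-7 cells the same neighbours had a median of -0.425 with 11 lower, while RB1 differed by -0.23. That RB1 call ends with the replicate number as a block (adjusted p = 0.057) and with no filter (0.059). DNA was not measured, and this stays a hypothesis found in these data.

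CDK6 rose in the resistant T47D lines by 2.75 (palbociclib), 2.25 (ribociclib) and 2.86 (abemaciclib). Gain of a region that holds the 20 nearest tested genes is argued against for palbociclib and abemaciclib, where these had medians of -0.28 and 0.04 and the nearest gene on one side, FAM133B, was at -0.80 and -0.20. A gain of CDK6 with only the 2 genes next to it on the other side is not excluded, since SAMD9 was at 3.44 and 2.68 and SAMD9L at 2.49 and 3.83, and CDK14, 8 genes away, was at 2.79 and 3.18. For ribociclib the median of 0.30 leaves it open, with 10 of 20 higher and side medians of 0.97 and 0.055. Values ran from -0.51 to 4.98, and FAM133B was at -0.35. SAMD9 is induced by interferon and rose in MCF-7 as well, and a change in regulation may be the reason instead, which was not tested.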
